A study of Mus musculus with 2 samples.

How the data were processed

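H3K27me3 was profiled by histone ChIP-seq in 2 biological replicates of the E14TG2a.4 line, and 9 peak lists were analysed, 4 of them from a single replicate and 5 from the whole series. Per the file headers, the mm10 lists came from 2 processing runs. The first run gave a relaxed list for each replicate, a relaxed list of both libraries together and a replicated list derived from those. The second gave a pseudoreplicated list for each replicate, another of both libraries together and a replicated list. The aligner, the peak caller, its thresholds and the use of the control are not given in the sources used here. No control sample was analysed here.

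The deposited lists give each peak a signal value, which is the authors' own and whose scaling is not given in the sources used here. It served only to rank and describe peaks. The mm10 lists also hold −log10 p and −log10 q of each peak as deposited, and every mm10 peak had a −log10 p of at least 2. A single list on build mm9, an archived series-wide list per the file headers, has 45974 regions covering 297.3 Mb, with its deposited p-value and q-value on a linear scale. It was not used further, because its coordinates belong to another build. Peak lists were read as called: depth per library is unknown, so no floor or interval for read counts was computed, and an absent peak can mean too few reads.

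The main calls used the pseudoreplicated list of each replicate, which was called on that replicate alone, so overlap between them compares the replicates. Genes came from GENCODE mouse release 21 on GRCm38, the build of the lists. No mm10 peak lay past a chromosome end or wholly in unsequenced bases, whereas 408 regions of the mm9 list lay past the end of a GRCm38 chromosome. The 19 autosomes and the X chromosome were used, and the second run had no peak on the Y chromosome or on unplaced sequence. Symbols that the annotation gives to 2 genes were counted for each gene.

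Overlap needed at least 1 bp. The overlap of replicates and the location of bases were tested by 1000 circular shifts within chromosomes, after removal of unsequenced stretches. Location was assigned in the order promoter, exon, intron, intergenic, over all annotated genes and transcripts. Gene lists (22, fixed before the data were examined) and families of at least 8 genes (355) were tested against all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over lists and over families. Genes are the units of these tests, not replicates, and neighbouring genes of a cluster are not independent. Names given to predicted genes and clones formed no family, a restriction set after the design was fixed. Some genes stand in more than 1 list. The CpG ratio was tested by 100000 resamples, and by 10000 under alternatives. Shares have exact (Clopper-Pearson) 95% intervals, which cover counting error only.

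Genes were named by a rule fixed before the data were examined: a fixed set of 11 genes, up to 4 marked members of each list with the highest mean percentile rank of signal, up to 2 members without a peak in alphabetical order (up to 4 in lists mostly marked), the 10 genes outside the lists with the most covered bases within 5 kb, and genes in the 10 longest domains. Families were named by the 10 smallest p values on each side. Myf5, Lefty1 and Lefty2 were named after their values were seen. A few genes that the rule takes are not reported here.

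Alternatives were windows of 2.5 kb and 0.5 kb, a −log10 q of at least 2, relaxed and replicated lists, each replicate left out, 50% of the window covered, any transcript start, a CpG-rich background, other joining distances of 1 kb and 5 kb, and other overlap rules. A test stratified by 10 classes of CpG ratio and the list of both libraries together were added after seeing the data. The tests were also run on simulated data with known answers. These simulations were written after a first set of values had been computed, and all values were then computed again. For gene families, 13 of 20 planted among 355 were recovered, and 0 of the other 335 were called. Each gene was called independently and without regard to CpG ratio there. The result therefore does not give the rate of false calls for clustered families or for families of a single promoter class. Of simulated lists with no effect of their own, drawn mostly from simulated promoter classes that are marked more often, 90% passed the plain Fisher's exact test and 2.5% the stratified test. The plain test therefore does not separate a list from its promoter class. In the data 17 of the 22 lists passed under either test. Analyses used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.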

Results

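The series measured trimethylation of lysine 27 of histone H3 (H3K27me3), the mark laid down by Polycomb repressive complex 2, by chromatin immunoprecipitation and sequencing in E14TG2a.4, a male mouse embryonic stem cell line of strain 129/Ola that the labels date to embryonic day 3.5. There were 2 samples, which the labels give as biological replicates 1 and 2 of a single group. The series holds no second condition, so the questions its design poses are where the mark lies in these cells and how far the replicates give the same regions. Each replicate's own peak list held 63651 peaks covering 53.6 Mb in replicate 1 and 98582 peaks covering 58.4 Mb in replicate 2. The number of reads behind each list is unknown. All positions are on mouse build mm10 (GRCm38), and a promoter is called marked when the 1 kb on each side of the annotated 5' end of a protein-coding gene overlaps a peak in both replicates. Genes said to have no peak have none in this window in either replicate.

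H3K27me3 covered the promoters of developmental regulators and was not called at those of the core pluripotency factors or of most housekeeping genes. Of 21755 protein-coding genes, 5679 (26.1%) were marked in both replicates, among them Hoxd13, Pax6, Gata6 and T, which direct limb, eye, endoderm and mesoderm development. Pou5f1, Nanog and Sox2, the core regulators of pluripotency, had no peak within 1 kb in either replicate, and neither did Gapdh or Actb. Cdkn2a, which encodes inhibitors of the cell cycle, was marked, with 1694 bp of its 2001 bp window covered in replicate 1 and 1675 bp in replicate 2.

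The replicates gave largely the same marked promoters. Replicate 1 marked 6057 promoters and replicate 2 marked 6574, and the 5679 common ones were 93.8% and 86.4% of these. Promoters marked in a single replicate, 378 in replicate 1 and 895 in replicate 2, were covered over a median of 298.5 bp and 280 bp, against medians of 1251 bp and 1200 bp for those marked in both. Across the 5679 common promoters the authors' signal values had a Spearman rho of 0.872 and a Pearson r of 0.869. These correlations run across genes, which are not independent replicates.

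Single peaks overlapped less often than promoters were shared, but the 2 measures are unlike. A promoter is shared when each replicate has any peak in its window, while single peaks must overlap each other. Of the peaks of replicate 1, 73.6% overlapped a peak of replicate 2 by at least 1 bp, and 53.7% of the peaks of replicate 2 overlapped a peak of replicate 1. When the other list was shifted around each chromosome 1000 times, these shares averaged 4.81% and 3.46% and never passed 7.43% and 5.36% (one-sided permutation test, p = 0.001 for each, the smallest the shifts can give). The bases covered in both replicates amounted to 39.2 Mb, 1.53% of the sequenced bases of the autosomes and the X chromosome, and the Jaccard index of covered bases was 53.9%. Over 41548 regions found in both, signal values had a Spearman rho of 0.722 and a Pearson r of 0.856, again across regions that are not independent.

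The common bases were concentrated at gene starts. Promoters within 1 kb of any annotated transcript start held 27.9% of them, against a mean of 6.51% after shifting, which is 4.29 times as much. Exons outside promoters held 8.64% against 3.47%. Introns held 34.2% against 40.6%, and intergenic sequence 29.3% against 49.4%. The 4 shares make up a whole, so the excess at promoters and exons lowers the other shares, and the tests below are not separate results. Whether introns or intergenic sequence hold less of the mark apart from that excess was not tested. Each of the 4 shares lay outside the range of the 1000 shifted values (two-sided permutation test, adjusted p = 0.002 for each, the smallest the shifts can give).

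The HOX clusters, whose genes set position along the body axis, were covered over most of their length. All 39 HOX genes were marked, which was 100% against 26.0% of the other protein-coding genes (Fisher's exact test, two-sided, adjusted p = 8.9e-23 over 22 gene lists). Neighbouring HOX genes are not independent, so this p value overstates the evidence. Between the outermost genes, peaks common to the replicates covered 92.9% of the Hoxc cluster on chromosome 15 (102921103 to 103036852), 90.4% of Hoxa on chromosome 6 and 88.8% of Hoxd on chromosome 2 (74668310 to 74765142). The Hoxb cluster on chromosome 11 (96194316 to 96368256), which includes the distant Hoxb13, was covered over 73.3%. Hoxb7, Hoxb13, Hoxb4 and Hoxc8 had the highest signal ranks of the list. The signal value at the Hoxb7 promoter was 18.9 in replicate 1 and 17.9 in replicate 2, above 99.9% of the peaks of each list. Hoxd13 reached 13.4 and 12.7.

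**Figure D1:**
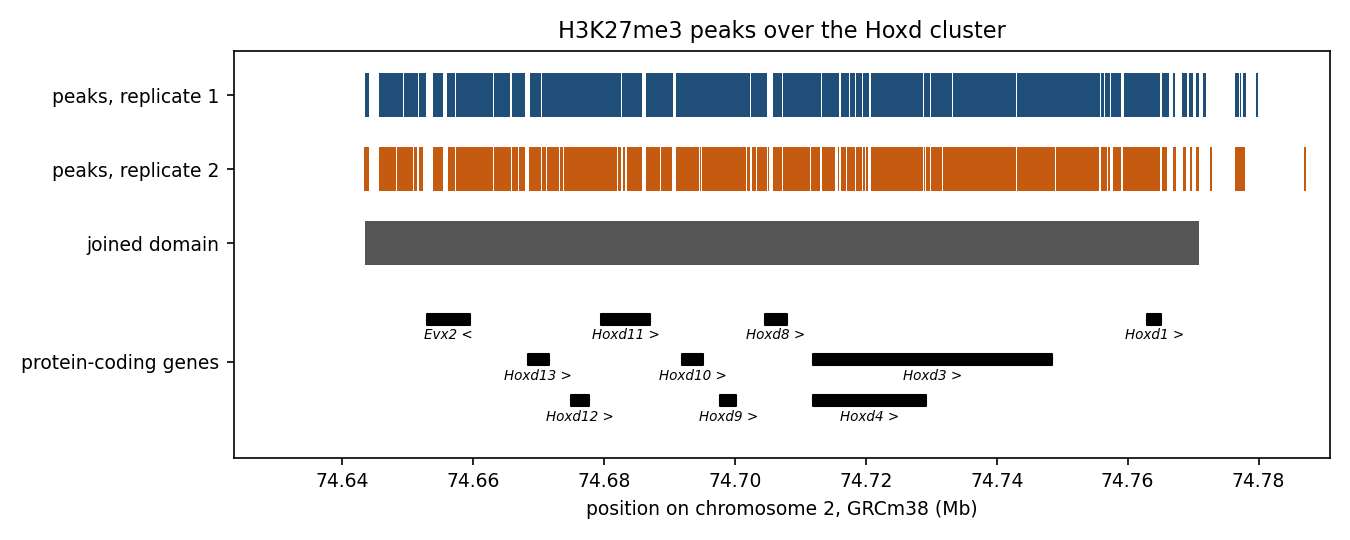
Peaks of replicate 1 and replicate 2 over the Hoxd cluster, with the domain made by joining the common bases and the protein-coding genes below (arrowheads give the strand); the horizontal axis is the position on chromosome 2 in Mb. Both replicates cover most of the stretch from Evx2 to Hoxd1, and the joined domain of 127.4 kb extends past both genes.

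Regulators of all 3 germ layers were marked. Each of the 32 neural and neural crest regulators was marked (100%, exact 95% interval 89.1 to 100), led by Lmx1b, Neurod2, Neurog1 and Dlx5. The Lmx1b promoter had signal values of 19.7 and 16.2. Of the muscle, heart and limb regulators 23 of 24 were marked, with Six2, Pax9, Pitx1 and Msx2 at the top of the ranks. The exception, Myf5, had a peak in replicate 2 alone. Of the mesoderm and endoderm regulators 21 of 24 were marked, led by Lhx1, Foxf1, Pdx1 and Evx1, and Cer1, Hnf4a and Tbx6 had no peak. Fisher's exact test gave adjusted p values of 8.9e-19, 2.5e-12 and 1.3e-09 for these lists.

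Secreted morphogens were marked at 24 of 28 genes (85.7%, Fisher's exact test, adjusted p = 2e-10). Wnt1, Wnt10b, Wnt10a and Wnt6 ranked highest, with signal values at Wnt1 of 17.5 and 17.1. Nodal, a signal of the early embryo, and Fgf10 had no peak, and Lefty1 and Lefty2, inhibitors of Nodal, had one in replicate 2 alone.

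Trophoblast genes were marked at 11 of 15 promoters (Fisher's exact test, adjusted p = 0.00032), among them the transcription factors Cdx2, Gata2, Hand1 and Ascl2. Elf5, Plac1, Prl3d1 and Tpbpa had no peak. Of the blood and endothelial genes 9 of 15 were marked (exact test, adjusted p = 0.0084), including Gfi1, Cebpa, Pax5 and Kdr, while Gata1 and the globin gene Hbb-bt were among those with no peak.

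For the list of naive pluripotency genes no difference from other genes was found, with 4 of 24 marked (16.7%, exact 95% interval 4.74 to 37.4, Fisher's exact test, adjusted p = 0.4). The 4 were Tbx3, Gbx2, Prdm14 and Esrrb. Their windows were only partly covered, by a median of 917 bp in replicate 1 and 767 bp in replicate 2. Dnmt3l and Dppa2 were among the 20 with no peak in either replicate. By contrast, 9 of 10 genes of the primed epiblast, the later state before gastrulation, were marked (exact test, adjusted p = 8.6e-05), led by Pou3f1, Fgf5, Dnmt3a and Otx2. The difference between these lists was not tested.

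Genes that every dividing cell uses carried little of the mark. None of 20 cell cycle and replication genes had a peak in either replicate, for example Aurka and Aurkb (0%, exact 95% interval 0 to 16.8, Fisher's exact test, adjusted p = 0.0059). Of 26 glycolysis and housekeeping genes B2m alone was marked (exact test, adjusted p = 0.0086), and Actb and Actg1 had no peak. Of 92 genes taken by the ribosomal protein pattern 4 were marked (exact test, adjusted p = 1.6e-07). These were Rps14 and Rpl3 together with Rps6ka4 and Rps6kl1, which encode protein kinases and not ribosomal proteins, while Rpl10 and Rpl10a had no peak. The pattern takes 10 genes named as S6 kinases in all, and without them 2 of 82 genes were marked. The calls for the cell cycle and the housekeeping lists ended when 50% of the window had to be covered. Their counts stayed at 0 of 20 and 1 of 26 under that rule. Marked promoters over all protein-coding genes fell from 5679 to 3036, which leaves lists of this size less room to be called lower. The lost calls therefore do not show more of the mark in these lists.

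Inhibitors of the cell cycle were marked more often, at 6 of 10 genes (60%, exact 95% interval 26.2 to 87.8, Fisher's exact test, adjusted p = 0.032). Trp73, Cdkn1c, Cdkn2a and Cdkn2c ranked highest, and Cdkn1a, Cdkn2d and Trp53 had no peak within 1 kb. Outside that window, common peaks covered 1355 bp within 5 kb of the Cdkn1a start. The call was lost, at 3 of 10 marked, with a window of 0.5 kb on each side and with 50% of the window covered (exact test, adjusted p = 0.5 and 0.187).

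Germline genes were marked at 15 of 18 promoters (83.3%, exact 95% interval 58.6 to 96.4, Fisher's exact test, adjusted p = 1.4e-06), led by Tex19.1, Syce1, Ddx4 and Slc25a31. With 50% of the window covered, 7 of 18 were marked (38.9%, exact test, adjusted p = 0.012). The median signal values of the marked germline promoters were 6.03 and 6.36 in replicates 1 and 2, and those of the HOX promoters were 14.8 and 14.7. Sycp3, a component of the synaptonemal complex of meiosis, had no peak. Of 13 genes of the two-cell stage Duxf3 alone was marked, and Gm5662 and Tcstv1 were among the 12 without a peak (exact test, adjusted p = 0.25). Many of these genes have near-identical copies, so an absent peak there is uncertain.

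Imprinted genes, expressed from a single parental copy, were marked at 14 of 26 promoters (53.8%, Fisher's exact test, adjusted p = 0.0047). Dio3, Kcnq1, Dlk1 and Ascl2 ranked highest, and Mest and Mkrn3 had no peak. The peak lists do not separate the parental copies.

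Genes of the Polycomb and Trithorax complexes themselves did not differ from other genes, with 10 of 32 marked (exact test, adjusted p = 0.57). Cbx8, Cbx2 and Pcgf5, all subunits of Polycomb complexes, were among the highest ranks. The Cbx8 promoter on chromosome 11 had signal values of 18.6 and 15.6, while Cbx6 and Cbx7 had no peak.

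Fibroblast markers, fixed as a sign of feeder cells, were marked at 6 of 15 genes (exact test, adjusted p = 0.28), among them Pdgfra, Thy1, Col1a1 and Col1a2 but neither Acta2 nor Col3a1. Genes of liver and pancreas function were marked at 4 of 18 (exact test, adjusted p = 1). These were Sst, Cela1, Apoa1 and Cpa1, whereas Afp and Alb had no peak.

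Clustered families lay at both extremes. Protocadherin cluster genes, which give neurons their surface identity, were marked at 53 of 57 promoters on chromosome 18 (93.0%, Fisher's exact test, adjusted p = 9.1e-26). Pcdha4, Pcdhga10, Pcdhgb6 and Pcdhga11 ranked highest, and Pcdha6, Pcdha7, Pcdha8 and Pcdhb9 had no peak. Of 1135 olfactory receptor genes 10 were marked (0.881%, exact 95% interval 0.423 to 1.61, exact test, adjusted p = 3.4e-133), including Olfr95, Olfr463, Olfr222 and Olfr9 but not Olfr1 or Olfr10. With replicate 1 left out 20 were marked (1.76%). None of 327 vomeronasal receptor genes, such as Vmn1r1 and Vmn1r10, was marked (exact 95% interval 0 to 1.12, exact test, adjusted p = 6.8e-43). The plain test set these lists against 27.5% and 26.5% of the other protein-coding genes. Had they followed their CpG classes, 7.73% of the olfactory and 6.92% of the vomeronasal receptor genes would be marked. The plain test therefore overstates how far they differ from promoters of similar CpG ratio, although both observed shares lay below these values too. Receptor families hold many similar sequences, so the authors' read filters could have removed signal there.

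**Figure D2:**
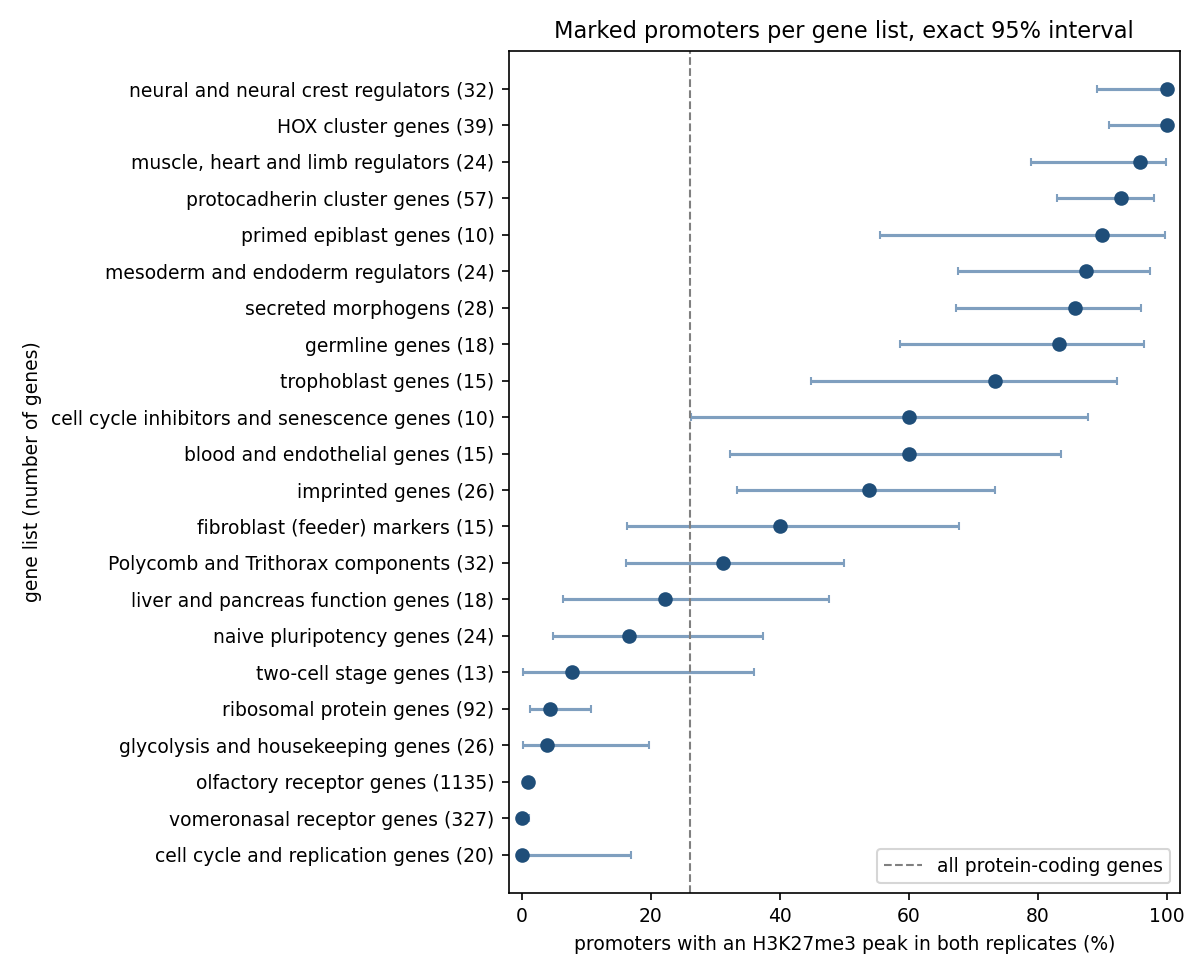
Share of promoters with a peak in both replicates, in percent, for each of the 22 gene lists (points) with its exact 95% interval (bars); the number of genes is in brackets and the dashed line is the share over all protein-coding genes, 26.1%. HOX and neural regulators stand at 100%, and the receptor lists and the list of cell cycle and replication genes near 0.

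Among 355 families of genes with the same symbol stem, 53 were marked more often and 26 less often than the remaining genes (Fisher's exact test, adjusted p under 0.05). The smallest p values on the high side belonged to Wnt (19 of 19 marked), Pcdhb (21 of 22), Nkx (14 of 14), Col (30 of 45), Pcdh (12 of 12), Pcdhga (12 of 12), Slc (143 of 371), Hoxa (11 of 11), Hoxb (10 of 10) and Galnt (14 of 17). Nkx genes are homeobox regulators, Col genes encode collagens and Slc genes membrane transporters. On the low side were Olfr, Vmn (0 of 331), Zfp (60 of 394), Rpl (1 of 54), Mrpl (1 of 49), Tas (0 of 38), Scgb (0 of 34), Hist (5 of 67), Cep (1 of 36) and Serpinb (0 of 26). Zfp genes encode zinc finger proteins, Tas genes taste receptors and Hist genes histones. The low-side count fell to 7 when 50% of the window had to be covered. Under that rule 3036 promoters were marked over all protein-coding genes, against 5679, so a lower share was harder to call. In the test stratified by CpG ratio 13 of the 26 families lost the low-side call and 5 of the 53 the high-side call, while 9 and 6 others gained one. Among those lost were Tas, Scgb and Serpinb, with 9.72%, 7.94% and 9.17% of their members marked if they followed their CpG classes.

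Marked promoters had a higher ratio of observed to expected CpG than the others, with medians of 0.634 and 0.474 over the 500 bp on each side of the gene start. The difference of 0.16 was larger than in any of 100000 resamples (two-sided permutation test, p = 1e-05, the smallest they can give). The relation was not monotonic. With promoters split into 3 equal classes by CpG ratio, 10.5% of the lowest, 39.3% of the middle and 28.4% of the highest were marked. With 10 equal classes, the share rose from 4.14% in the lowest to 45.3% in class 5 and was 25.6% in the highest.

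**Figure D3:**
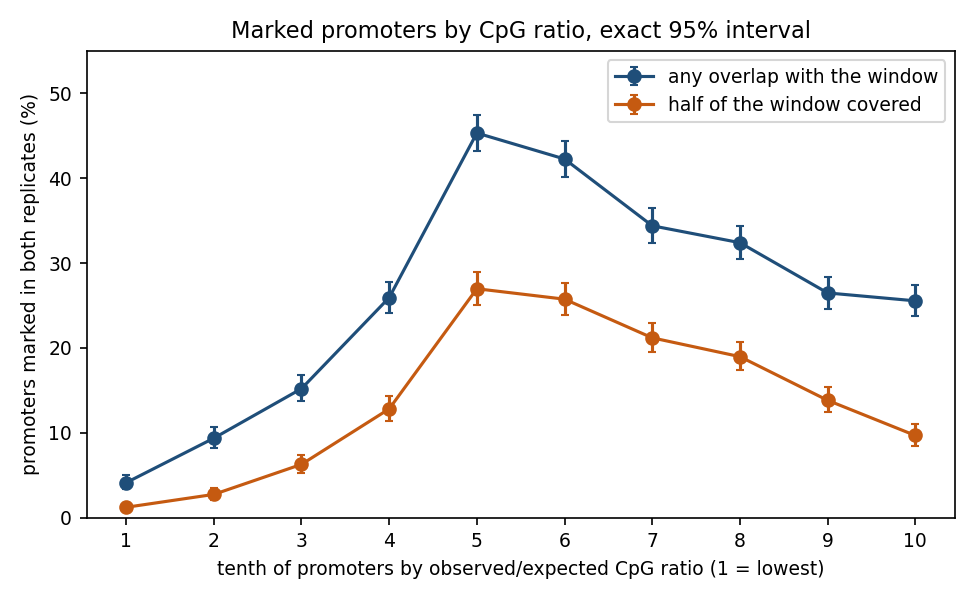
Share of promoters marked in both replicates, in percent, in 10 equal classes of the observed to expected CpG ratio, for any overlap with the window (blue) and for 50% of the window covered (orange), with exact 95% intervals. Both lines peak in class 5, where any overlap gives 45.3%.

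Joining common bases within 3 kb gave 16987 domains with a median length of 1521 bp, of which 1367 reached 10 kb and 34 reached 50 kb. A protein-coding gene start lay in 21.2% of all domains, in 65.7% of those of 10 kb or longer and in 88.2% of those of 50 kb or longer. A longer stretch holds a gene start more often by length alone, and these shares were not compared with shifted domains. The 4 longest lay over the HOX clusters: Hoxc at 172.0 kb, Hoxb at 137.7 kb, Hoxa at 134.7 kb and Hoxd, with its neighbour Evx2, at 127.4 kb. The Hoxb domain held 9 of the 10 Hoxb genes, and Hoxb13 lay in a separate domain of 55.2 kb. The fifth spanned 112.1 kb on chromosome 7 (143357175 to 143469261) around Cdkn1c, an imprinted inhibitor of the cell cycle. Next came domains at Lmx1b on chromosome 2 (33556125 to 33650837), at Kncn, 6430628N08Rik and Dmbx1 on chromosome 4 (115874515 to 115953871), and at Cbx8 on chromosome 11. The ninth, on chromosome 7 (79494584 to 79561813), held no protein-coding start, and the tenth held Zic1 and Zic4 on chromosome 9 (91350266 to 91416245). These counts depended on the list and the joining distance. With replicate 1 left out there were 32488 domains, 2369 of them of 10 kb or longer, and those of 10 kb or longer numbered 686 when joined within 1 kb and 3966 with the replicated list of the first run. The ranks did too: of these 10 domains, 6 to 8 were among the 10 longest under each alternative, and the longest domain ran from 141.9 kb when joined within 1 kb to 246.2 kb with replicate 1 left out.

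Outside the fixed lists, the protein-coding genes with the most covered bases within 5 kb of the start were Prdm12 (10001 bp), Dlx4 (9892 bp), Dmbx1 (9844 bp), the neighbours Nr2e1 and Ostm1 (9814 bp each), Ankrd63 (9750 bp), Insrr (9746 bp), Gm4881 (9739 bp), Six3 (9706 bp) and Pax2 (9690 bp). Prdm12, Dlx4, Dmbx1, Nr2e1, Six3 and Pax2 encode regulators of transcription. Pax2 had signal values of 16.4 and 17.6.

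The X chromosome had a lower share of marked promoters than any autosome. Of 948 X-linked promoters 100 were marked (10.5%, exact 95% interval 8.67 to 12.7), against 26.8% of 20807 autosomal promoters (interval 26.2 to 27.4). Autosomal shares ran from 19.7% on chromosome 7 to 37.2% on chromosome 18. Common peaks covered 0.22% of the sequenced bases of the X and 1.62% of those of the autosomes. Intervals here cover counting error over genes only. The line is male, with a single X, so lower copy number could reduce the peaks called there.

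**Figure D4:**
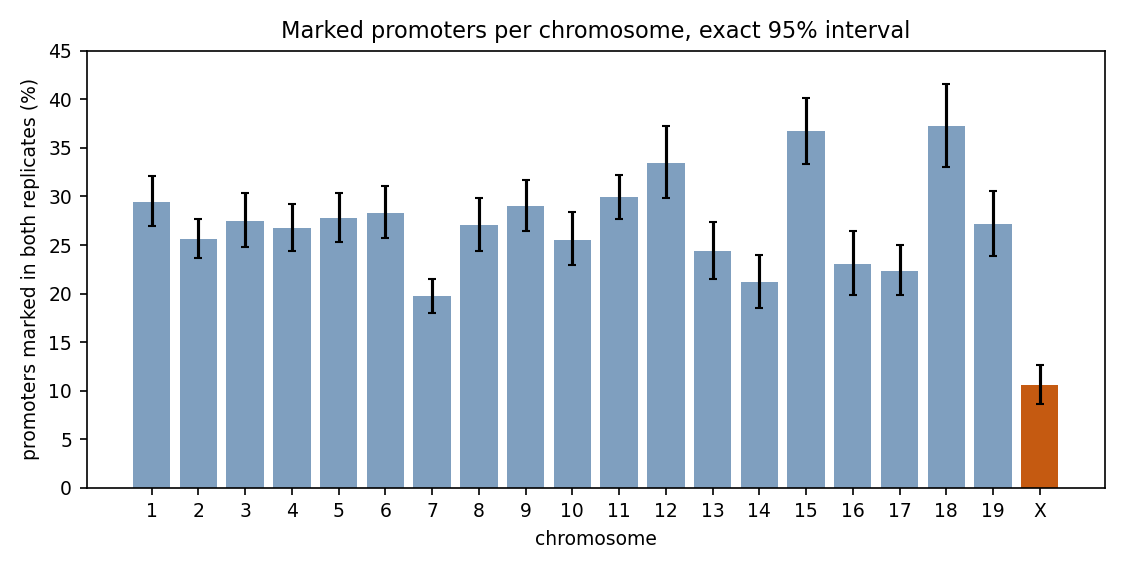
Share of protein-coding promoters marked in both replicates, in percent, per chromosome (bars, from 0), with exact 95% intervals (lines). The X chromosome, in orange, stands at 10.5%, below every autosome.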

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

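The relaxed lists of the first run held peaks outside the chromosomes used above, and none of the 4 lists of the second run did. On unplaced sequence there were 32 relaxed peaks in replicate 1 and 27 in replicate 2.

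Of the 1000 relaxed peaks of replicate 1 with the smallest p values, 4 overlapped no second-run peak of that replicate. The first of all by p was one of them, on chromosome 17 (39843012 to 39846744), over the annotated genes Gm26917 and CT010467.1, with a signal value of 7.41 and a −log10 p of 103.1. A further one lay close by (39847468 to 39848848), and the others were on chromosome 3 (5860521 to 5860875) and chromosome 4 (118548463 to 118548861). In replicate 2 the chromosome 17 site also had a relaxed peak (39843089 to 39846651, signal value 3.57) and no second-run peak.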

How the results depend on the processing

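The stratified test and the list of both libraries together were chosen after seeing the data. Of 111 alternative values for the main results 89 stayed the same in direction and side of the threshold or within the set range, and 22 moved. The single gene lists are outside that count. They are among 304 further values, of which 293 stayed the same, 4 no longer passed the threshold, 4 reversed direction and 3 moved. The overlap of the replicates, the location of the common bases and the CpG difference kept their direction and side of the threshold under every alternative run. The cause was not tested for the changes below, except where a stricter or wider rule by construction takes fewer or more promoters or joins fewer regions.

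Marked promoters numbered 3036 with 50% of the window covered, against 5679, which leaves less room for a lower share to be called. Lists marked less often then numbered 3, against 5, lists marked more often 11, against 12, and families marked less often 7, against 26. The latter were 42 with relaxed lists, 40 with the replicated list of the second run and 42 with any transcript start. The rank correlation of the replicates was 0.742 with −log10 p and 0.541 with relaxed lists. Domains numbered 37974 and 34674 with the replicated lists of the first and second run, and those of 10 kb or longer 3966 and 3450, against 686 when joined within 1 kb. Leaving out a replicate gave 22833 to 32488 domains and 1834 to 2369 of 10 kb or longer. The X share was 8.23% with 0.5 kb windows, 3.69% with 50% of the window covered, 14.9% with relaxed lists, 14.6% and 13.9% with the replicated lists, 14.3% with both libraries together and 11.3% to 13.6% without a replicate, below the autosomal share in each. The Polycomb and Trithorax list, never past the threshold, turned to the lower side at 18.8% with 0.5 kb windows, 31.2% with relaxed lists and 12.5% with 50% of the window covered. Liver and pancreas genes, at 22.2%, turned to the higher side when stratified by CpG ratio. Depth is unknown and limits what an absent peak shows.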

Other observations

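The patterns and tests of this part were found in these data. The comparison of gene types, the named non-coding genes and the test that joins nearby peaks were chosen after the values, or values closely tied to them, had been seen.

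The marked share of non-coding genes differed by annotated type. Genes of long RNAs that start from a bidirectional promoter were marked at 63 of 190 (33.2%, exact 95% interval 26.5 to 40.3). Only 5 of the 190 lie more than 5 kb from the annotated 5' end of any protein-coding gene. The share of this type therefore cannot be separated from that of the coding neighbours. Other starts of coding transcripts did not enter this distance, so genes counted as far can still lie beside one. Antisense genes were marked at 20.6% of 2958, and at 12.1% of the 1890 that lie more than 5 kb from such a 5' end. Of 5305 lincRNA genes 633 were marked in both replicates (11.9%, exact 95% interval 11.1 to 12.8), and of the 4678 that lie more than 5 kb from such a 5' end 424 were (9.06%). Processed pseudogenes were marked at 4.04% of 9849. At the HOX clusters Hotair, Hotairm1 and Hottip, the last of which starts outside the outermost Hoxa gene, were covered over the whole 2001 bp window in both replicates, and Haglr over 1841 bp and 1930 bp. The long domain on chromosome 7 without a protein-coding start held Mir9-3hg, the host gene of a microRNA, whose window was covered over 2001 bp in replicate 1 and 1797 bp in replicate 2. Xist and Kcnq1ot1, both non-coding RNAs that silence genes in cis, had no peak within 1 kb in either replicate.

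X-linked promoters were marked at 10.5%, below every autosome. Their CpG content argues the other way, since autosomal promoters weighted to the same CpG classes were marked at 27.6%. Leaving out families of 8 or more genes and predicted genes left 11.2% on the X (exact 95% interval 8.4 to 14.4) against a weighted autosomal share of 34.1%, which argues against copies of gene families as the whole cause. A male line has a single X. In the list of both libraries together the X share was 14.3% (interval 12.2 to 16.7), against 11.3% and 13.6% in the single lists of replicates 1 and 2, and stayed under the weighted autosomal shares of 29.5% and 32.4% in those single lists. Marked X promoters also had lower median signal (5.48 against 7.69 in replicate 1), so lower copy number may still contribute in part, and no biological explanation was tested.

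Replicate 2 had 1.55 times as many second-run peaks as replicate 1, while the relaxed lists differed by a factor of 1.02. Splitting of regions into several peaks was not the whole cause, since after joining peaks within 1 kb the ratio was still 1.5 (47783 against 31871 regions). Of the 45614 peaks found in replicate 2 alone, 57.2% overlapped a relaxed peak of replicate 1, against at most 7.95% after shifting. A similar share of all relaxed peaks of replicate 2, 57.5%, overlapped a relaxed peak of replicate 1. Peaks found in replicate 1 alone were not compared in this way. The threshold of the second run is a candidate explanation for the overlapping peaks. This comparison cannot tell it from other differences between the libraries, such as depth, which is unknown. The other peaks found in replicate 2 alone stay open, and no biological explanation was tested.

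The share of marked promoters peaked at an intermediate CpG ratio. Among promoters with a GC content of 55% to 62%, 52.3% were marked in classes 5 and 6 of the 10 classes of CpG ratio and 13.1% in classes 9 and 10, a difference of 39.2 percentage points that argues against GC content bias as the whole cause. With 50% of the window covered the difference was 14.6 points (26.4% against 11.8%), so peaks touching only the edge of the window do not account for it. One hypothesis, not tested because expression was not analysed here, is that the promoters richest in CpG may belong to active genes more often.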
